A study of Mus musculus with 8 samples.

How the data were processed

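RNA-seq was read from 8 libraries of mouse kidney at postnatal day 3, made from poly(A)-selected RNA. The labels give each library a sex, a genotype and a replicate number of 1 or 2, which makes 4 groups of 2 libraries and 4 libraries per genotype. The control genotype is labelled Slc12a3 Cre/+; C1 +/+ and the mutant genotype Slc12a3 Cre/+; C1 YAP/+. Slc12a3 encodes the NaCl cotransporter of the distal convoluted tubule, and both genotypes carry the Cre allele. The labels do not explain C1 and do not say whether the YAP transgene is a mouse or a human sequence. Per the labels' protocols, RNA was fragmented and turned into double-stranded cDNA, and libraries were built with a DNA library kit and size-selected on gels.

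The authors deposited 1 table of RPKM (reads per kilobase of gene length per 1e6 reads) for 35976 gene symbols, with a gene length column. The submitters' processing notes name STAR, featureCounts and the mouse build mm10, without versions. Annotation release, strand setting and treatment of reads that map to several genes are not given in the sources used here, so genes with near-identical copies, overlapping genes and antisense genes carry that uncertainty. The samples, covariates, thresholds, gene lists, variants of the analysis and the rule for named genes were fixed before the data were examined. That plan had assumed read counts and a count model. As the deposited unit was RPKM, the main test was changed to limma on a log scale, and voom on the recovered reads was run beside it. The pseudocount, the filter on recovered reads and the scaling of RPKM were set once the unit was known and before any test, and were kept after alternatives had been seen.

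RPKM multiplied by gene length came out as a whole multiple of 1 step per library: all 179720 nonzero values lay within 0.01 of a whole read, with a largest deviation of 5.6e-09. Reads per gene and library totals were worked back from these steps. Totals, in units of 1e6 reads, were 78.2 to 87.1 in the replicate 1 libraries and 22.8 to 25.2 in the replicate 2 libraries. Between 96.7% and 97.1% of each total lay in the listed genes. Replicate number therefore coincides with a depth batch, each batch holding 1 library of every group, and within-batch values are given beside pooled ones. Precision is lower in the shallow libraries for genes with few reads. Libraries of the same group differed by more than counting noise (chi-square per degree of freedom 22.6 to 51.2 over genes with at least 20 reads), which separate preparations of the same RNA would also do. The labels do not say that the 2 libraries of a group come from separate animals, and p-values measure the spread between these libraries.

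A gene was tested if it reached 0.2 reads per 1e6, the level of 10 reads at the median listed total, in at least 2 libraries and 15 reads in all. This left 18156 genes, and 8978 of the listed symbols had 0 reads in every library. Trimmed-mean-of-M-values factors (trims 0.3 and 0.05, own implementation) were computed on the recovered reads and ranged from 0.975 to 1.02. RPKM was divided by these factors, and levels are given as scaled RPKM, mean ± SD over 4 libraries per genotype. Log2(scaled RPKM + 0.1) was fitted with limma 3.58.1 in R 4.3.3 (empirical Bayes with trend and robust options). Fold changes are on this log2 scale with its pseudocount of 0.1, which understates the change of genes near 0. Genotype over both sexes and sex were fitted in 1 additive model of genotype and sex. Genotype within males, within females and the interaction came from a model of group means that shares 1 estimate of the spread. P-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Fits within 1 depth batch used 4 libraries and the additive model, which leaves 1 degree of freedom per gene before the variance is shared across genes.

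Gene lists for nephron segments, other cell types and pathways were part of that plan, and 36 of them with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01. Camera with an estimated correlation and fry were run beside it, and adjusted over the lists. A trend in the variances was used in camera after a first run without it. As an addition chosen after the data were seen, the size of each list's median change was compared over all 35 splits of the 8 libraries into 4 and 4. The rule for named genes took Yap1 and its paralog Wwtr1, the 12 largest rises and 12 largest falls past the threshold with non-overlapping genotypes and a mean of at least 1 read per 1e6, up to 4 members of each list with the lowest p, any member of the YAP/TEAD target, distal convoluted tubule and connecting tubule lists, the sex markers, and up to 5 genes past the threshold for the interaction and for sex. Gene models without a proper name were replaced by the next gene, which skipped 2. The rule gave 199 genes, 169 of them past the threshold, and list members that missed the threshold are given with their values. Of these genes, 3 are not reported here. Another 12 genes, Vcam1, Fgf1, Bmp7, Pdgfa, Cdh16, Cldn8, Agt, Pax8, Smtn, Cd3d, Ptprc and Col3a1, were named after their values were seen, because a small count in a list needed its members. Aqp6 was also named outside the rule, as a member that a list and a symbol family share. Positions are from the RefSeq gene table of GRCm38.p6, the assembly that mm10 names, and 32501 of the table's symbols (90.3%) matched it.

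Functions for scaling, filtering, testing and list tests were tested on simulated data drawn from the levels, totals and spread of these libraries with 200 changed genes. For the genotype effect over both sexes, 95.3% of genes changed 4-fold, 77.3% of those changed 2-fold and 40.9% of those changed 1.5-fold were recovered, among 17907 tested, and 6.71% of calls were unchanged genes. The simulation gave 149 calls there and drew genes independently, while the data gave 4745 calls of 18156 tested. Rates from the simulation therefore need not hold for the data. In males alone the 2-fold recovery was 57.6% and in females alone 53.0%, among 17897 and 17893 tested. For the interaction it was 7.69% at 2-fold and 75.8% at 4-fold, among 17916 tested. For the sex effect it was 74.2% at 2-fold, among 17886 tested. In the fits within 1 depth batch, 11.2% of calls in the deep and 8.99% in the shallow libraries were unchanged genes, among 17892 tested. The analysis was repeated with median-of-ratios scaling, library totals only, no filter, a strict filter (1 read per 1e6 in at least 4 libraries), limma-voom on the recovered reads, a replicate block, no sex term, removal of sex-marker genes, a minimum change of 1.2-fold, removal of each library in turn, and list tests without shared members. Chosen after the data were seen were pseudocounts of 0.01, 0.5 and 1, each depth batch alone, and camera without a variance trend. Every per-sample column of the table was used.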

Results

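The series profiled kidneys of newborn mice in which a YAP allele is active in distal nephron segments, and its title asks for effects inside and outside those segments. Levels were measured for 8 libraries: 2 male control, 2 male mutant, 2 female control and 2 female mutant. The 4 replicate 1 libraries were sequenced deeper than the 4 replicate 2 libraries, and the 2 batches are called deep and shallow here. Of 35976 listed genes, 18156 had enough reads to be tested. The first principal component of the tested genes carried 61.6% of the variance and separated the genotypes, with all 4 mutant libraries on one side and all 4 control libraries on the other. The second carried 12.1%.

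Yap1, the gene whose activity the mutants were made to raise, was at the same level in both genotypes. Scaled RPKM was 35.5 ± 3.98 (SD, n = 4) in controls and 35.5 ± 0.77 (SD, n = 4) in mutants. The log2 fold change was 0.01 with a standard error of 0.09, and the 95% interval of the fold ran from 0.871 to 1.16 (limma, adjusted p = 0.973). It was 0.13 in the deep and -0.12 in the shallow libraries. Mouse Yap1 lies on chromosome 9 from 7931999 to 8004638 (GRCm38.p6, protein coding). Whether transgene reads would count on this gene is not known here, so its level does not test the labels.

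Genes that YAP and its TEAD partners are known to activate were higher in mutant kidneys. Ankrd1, a muscle and stress response gene, rose 81.3-fold from 0.522 ± 0.127 to 50.5 ± 9.61 scaled RPKM (SD, n = 4). Cyr61 and Ctgf, which encode secreted matricellular proteins, rose 13.6-fold and 7.74-fold. F3, the tissue factor gene, rose 10.7-fold and Gadd45b 10.7-fold, and Amotl2, an angiomotin family member, rose 3.54-fold. Of 22 measured targets, 15 rose, 0 fell and 7 did not pass, and 16 passed when adjusted over the list alone. Smaller rises passed for Ajuba (log2 1.19), Nuak2 (1.32), Igfbp3 (0.92), Myof (1.26), Tgfb2 (1.14), Lats2 (0.79) and Crim1 (0.70). The 7 that did not pass were Fjx1 (log2 0.24, adjusted p 0.0531), Axl (0.31, 0.123), Ptpn14 (0.38, 0.135), Amotl1 (0.18, 0.455), Asap1 (-0.04, 0.805), Arhgef17 (-0.04, 0.846) and Rbms3 (-0.01, 0.951). Leaving out male control replicate 1 brought Fjx1 past the threshold (adjusted p 0.0264), and leaving out female control replicate 2 did so for Axl (0.034) and Ptpn14 (0.0492). As a list, the targets were higher (camera, adjusted p = 1.69e-11; adjusted p = 0.0922 with an estimated correlation), with a median log2 change of 0.90 in the deep and 0.88 in the shallow libraries.

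Components of the Hippo pathway were also higher: 10 of 18 rose, 0 fell, and 11 passed when adjusted over the list alone. The list holds the kinase cascade that restrains YAP and also Yap1, Wwtr1, the TEAD partners and other regulators. Lats2, a kinase of the cascade, is in the target list as well. Tead4, a DNA-binding partner of YAP, rose 3.22-fold, Wwc1 1.92-fold, Amot 2.13-fold and Vgll4 1.53-fold. The list was higher (camera, adjusted p = 3.37e-05; adjusted p = 0.297 with an estimated correlation), with a median of 0.38 in the deep and 0.31 in the shallow libraries. Wwtr1, the paralog of Yap1, rose by a log2 change of 0.30 (adjusted p = 0.0247). Its call was lost without female control replicate 1 (adjusted p 0.0796), female mutant replicate 2 (0.0517), male control replicate 1 (0.05), male control replicate 2 (0.0651) or male mutant replicate 2 (0.0678), and in the deep (0.0928) and shallow (0.21) libraries.

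**Figure D1:**
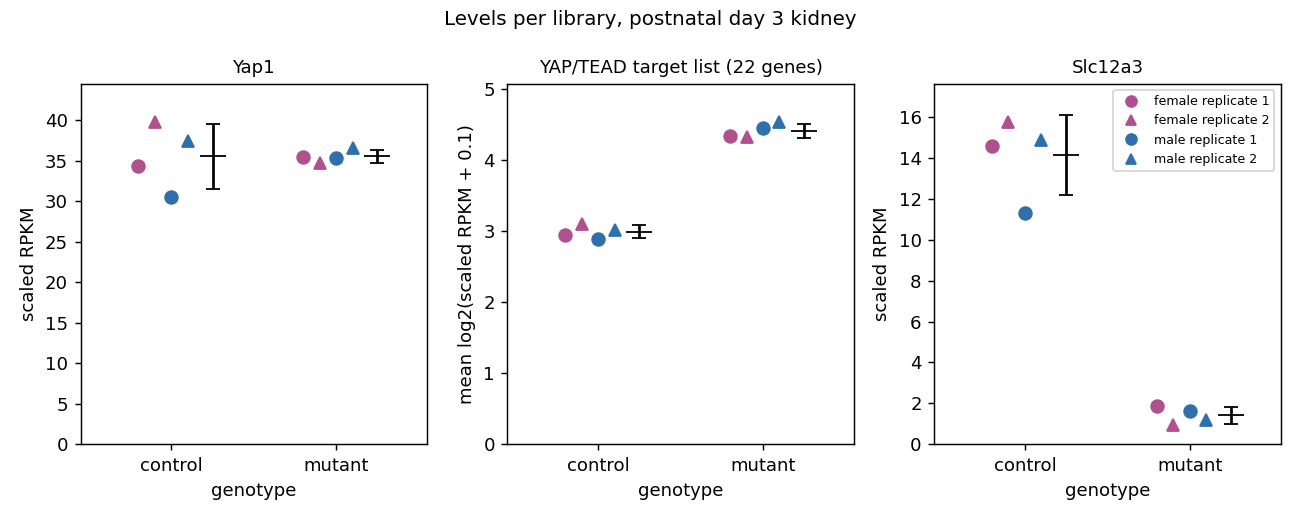
Levels per library by genotype for Yap1 and Slc12a3 (scaled RPKM) and for the mean log2 level of the 22 measured YAP/TEAD targets, with points for libraries, color for sex, shape for replicate, and mean and SD beside them (n = 4). Yap1 means are 35.5 in both genotypes, the lowest mutant target mean (4.33) lies above the highest control mean (3.11), and Slc12a3 is 14.1 in controls against 1.41 in mutants.

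Across all tested genes, mutant and control kidneys differed broadly. With limma, 4745 of 18156 genes passed the threshold, 2390 higher and 2355 lower, and of these 721 rose and 552 fell by more than 2-fold. Genotypes did not overlap in 30.5% of tested genes, against 2.86% by chance. The deep libraries alone called 3295 genes and the shallow ones 3110, and log2 changes of the 2 batches correlated at 0.841 across genes, which are not independent replicates. All 4745 calls had the same sign in both batches, which are subsets of the same libraries. The largest rises were mostly in genes with few reads in controls: Serpinb9b, a serpin with close paralogs, 228-fold; Wnt7a, a secreted signal, 140-fold; Crct1 113-fold; Ccl20, a chemokine, 96.6-fold; Havcr1, the kidney injury molecule 1 gene, 46.6-fold; and Slc2a3, a glucose transporter, 30.4-fold. Tfap2e rose 29.5-fold, S100a7a 22.6-fold and Krt17, a keratin, 21.8-fold. Nppb, a natriuretic peptide gene, had 3 control and 1733 mutant reads, a ratio of 554 (95% counting interval 189 to 2690). Il24, a cytokine, had 1 and 1147 reads, a ratio of 1100 (197 to 43500). Intervals cover counting error only.

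The largest falls included genes of metabolism in the proximal tubule and liver. G6pc, the glucose-6-phosphatase, was 18.6-fold lower and Pck1, a gluconeogenic enzyme, 9.71-fold lower. Mogat2 was 13.2-fold lower, the transporter genes Slc51a and Slc10a1 12.3-fold and 10.7-fold lower, and Nccrp1 23.6-fold lower. Ren1, the renin gene, fell from 187 ± 30.3 to 18.1 ± 10.4 scaled RPKM (SD, n = 4), and Ttr from 204 ± 47.8 to 14.2 ± 6.99 (SD, n = 4). Klk1, a kallikrein with close paralogs, and Angptl7 were 21.6-fold and 19.1-fold lower. Both calls were lost without male control replicate 1 (Klk1 adjusted p 0.0565, Angptl7 0.0545). Within the shallow libraries Ren1 (adjusted p 0.25), Ttr (0.299) and Angptl7 (0.571) did not pass, and within the deep ones Ttr (0.0758) did not, though each kept its sign. The size of the Klk1 fall moved with the libraries, at a log2 of -3.71 without female mutant replicate 2, -5.12 without female mutant replicate 1 and -5.06 without male mutant replicate 1, and -3.20 in the deep and -5.66 in the shallow libraries. Angptl7 was at -5.17 without female control replicate 2, and at -5.16 in the deep and -3.35 in the shallow libraries.

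The size of changes in genes near 0 in 1 genotype depends on the pseudocount, while the calls of the following genes did not. With pseudocounts of 0.01 and 1 in place of 0.1, the log2 rise was 8.67 and 5.49 for Serpinb9b, 8.38 and 4.53 for Wnt7a, 8.32 and 4.20 for Crct1, 8.15 and 3.96 for Ccl20, 9.04 and 3.33 for Nppb, and 8.28 and 2.48 for Il24. It was 7.62 and 2.02 for Tfap2e, 7.002 and 1.766 for S100a7a, 5.87 and 1.98 for Krt17, and 5.86 and 4.02 for Havcr1. Nccrp1 was at -5.30 and -2.55, Slc10a1 at -3.72 and -2.09, Slc51a at -3.79 and -2.64 and Tmem207 at -4.32 and -1.16. With the pseudocount of 1, Ankrd1 was at 5.06, Slc2a3 at 4.32, Edn1 at 2.67, Acta1 at 1.72, Fcgr1 at 1.34, Cd3g at 0.61, Ly6g at 0.46, Tubb3 at 0.37, Cd3e at 0.18 and Lep at 0.17. The falls were then -3.10 for Angptl7, -3.00 for Mogat2, -2.66 for Slc12a3, -1.79 for Slc4a1, -1.70 for Slc26a4, -1.12 for Egf, -0.52 for Cd8a, -0.38 for Abca13, -0.35 for Nos1 and -0.33 for Chga.

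Markers of the distal convoluted tubule, the segment named by Slc12a3, were mostly lower in mutants. Slc12a3 itself (chromosome 8, 94329109 to 94366222) was 9.65-fold lower, at 1.41 ± 0.418 against 14.1 ± 1.96 scaled RPKM (SD, n = 4). Pvalb, encoding parvalbumin, was 9.74-fold lower, Egf 4.19-fold lower and Kcnj10, a potassium channel, 2.58-fold lower. Of 16 markers 12 fell and 2 rose (Stk39, log2 0.37; Trpm6, a magnesium channel, 0.64), and 14 passed when adjusted over the list alone. Emx1 (-1.39), Tmem52b (-1.09), Wnk4 (-1.02), Fxyd2 (-0.97), Kcnj16 (-0.80), Klhl3 (-0.95) and Abca13 (-1.04) were others that fell, and Sall3 (-0.17, adjusted p 0.394) and Cnnm2 (-0.02, 0.921) did not pass. The list was lower (camera, adjusted p = 7.45e-06; adjusted p = 0.202 with an estimated correlation), with a median of -0.98 in the deep and -1.15 in the shallow libraries. Pvalb did not pass within the deep libraries (adjusted p 0.4), and Egf was at -1.40 in the deep and -2.74 in the shallow ones. Stk39 passed in neither batch (0.0696 and 0.0803).

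Among late distal and connecting tubule markers, 7 of 11 fell and 2 rose, the same 9 counted when adjusted over the list alone. Kl, the klotho gene, fell 3.67-fold, Calb1, a calcium-binding protein, 3.64-fold, S100g 2.62-fold, Hsd11b2 2.15-fold and Slc8a1 1.85-fold. Kcnk1 (log2 0.68) and the calcium channel gene Trpv5 (0.84) rose. Scnn1g (log2 -0.30, adjusted p 0.204) and Atp2b1 (-0.14, 0.454) did not pass. The list was lower (camera, adjusted p = 0.0062; adjusted p = 0.28 with an estimated correlation). In the thick ascending limb 10 of 15 markers fell and 0 rose, with 10 adjusted over the list alone: Tmem207 9.08-fold, Ptger3 3.48-fold, Ppp1r1a 3.19-fold and Kcnj1 2.53-fold (camera, adjusted p = 6.49e-05; adjusted p = 0.21 with an estimated correlation). List medians in the deep and shallow libraries were -0.76 and -1.02 for the connecting tubule and -0.80 and -0.96 for the thick ascending limb. Of 6 macula densa markers, Nos1 fell (log2 -1.06), Ptgs2 rose (0.82), 1 other gene moved each way and 2 did not pass, with 4 adjusted over the list alone (camera, adjusted p = 0.62; adjusted p = 0.864 with an estimated correlation). The macula densa median was 0.04 in the deep and -0.4 in the shallow libraries.

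Marker lists of both cell types of the collecting duct had lower medians in mutants. Of 16 intercalated cell markers 15 fell and 0 rose, 16 adjusted over the list alone: the bicarbonate exchanger Slc4a1 fell 7.05-fold, Slc26a4 5.94-fold, the ammonium transporter Rhbg 4.41-fold and Rhcg 2.37-fold, and Aqp6 3.55-fold (camera, adjusted p = 2.17e-13; adjusted p = 0.0778 with an estimated correlation). Of 14 principal cell markers 7 fell and 1 rose, 10 adjusted over the list alone. Aqp4 fell 2.67-fold, Elf5 1.81-fold and Hsd11b2 2.15-fold, and Krt7, a keratin, rose 4.17-fold (camera, adjusted p = 0.00353; adjusted p = 0.286 with an estimated correlation). Medians in the deep and shallow libraries were -1.26 and -1.34 for intercalated cells and -0.41 and -0.60 for principal cells.

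The proximal tubule, which does not express Slc12a3, showed the lowest list median. Of 30 markers 26 fell and 0 rose, 27 adjusted over the list alone. Miox, an inositol oxygenase, fell 8.48-fold from 753 ± 39.8 to 91.0 ± 23.7 scaled RPKM (SD, n = 4), Gatm 5.21-fold, the organic anion transporter Slc22a8 6.42-fold and Pck1 9.71-fold. The list was lower (camera, adjusted p = 2.58e-17; adjusted p = 0.0743 with an estimated correlation), with a median of -1.39 in the deep and -1.55 in the shallow libraries. Fatty acid oxidation genes fell in 16 of 21 cases with 0 rising, 18 adjusted over the list alone: Acaa1b 2.87-fold, Hadh 1.92-fold, Acaa2 1.81-fold and Decr1 by a log2 of -0.675 (camera, adjusted p = 5.07e-09; adjusted p = 0.172 with an estimated correlation), with medians of -0.66 and -0.54. The share of reads on mitochondrially encoded genes was 2.08 ± 0.387% in controls and 1.30 ± 0.098% in mutants (SD, n = 4; exact permutation test, two-sided, p = 0.0286, the smallest that 70 splits allow).

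**Figure D2:**
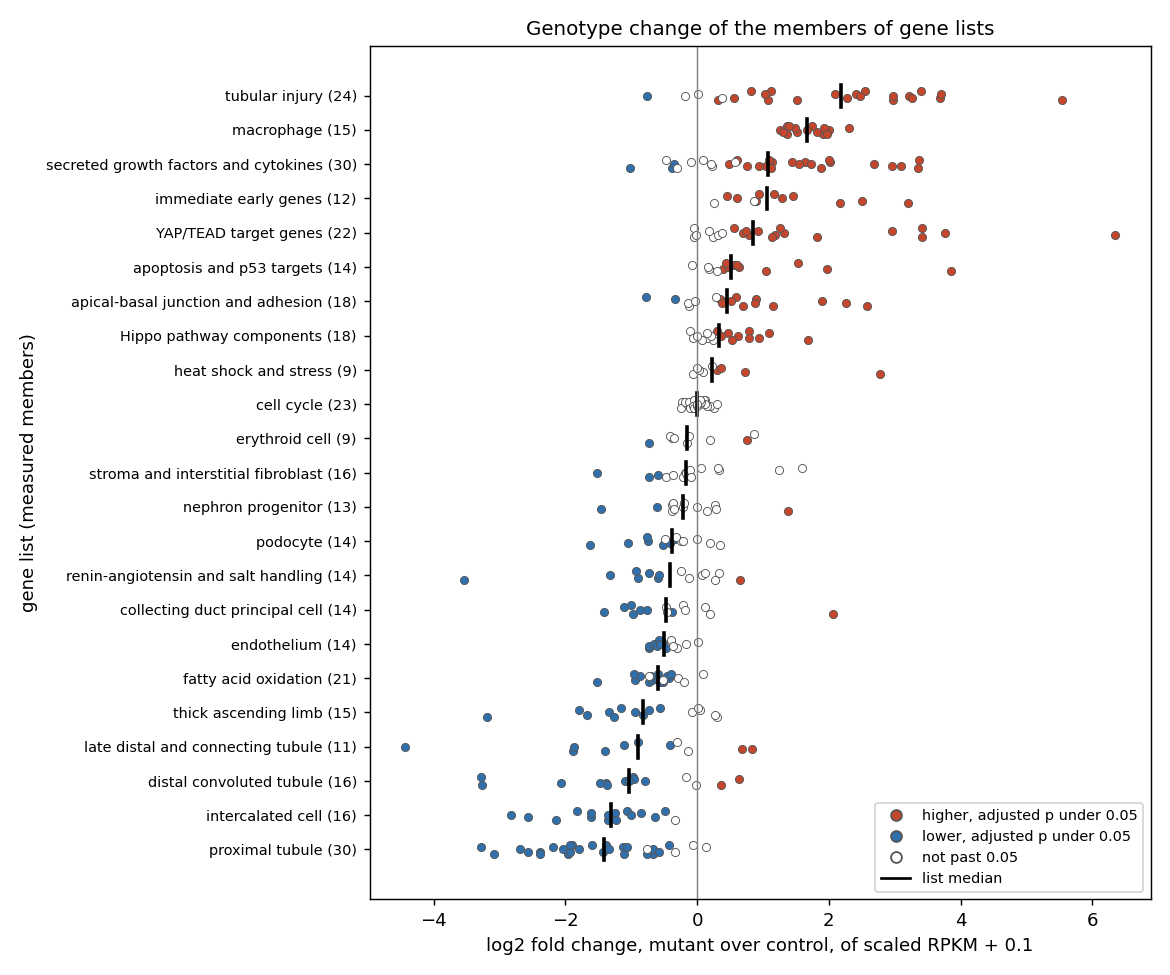
Log2 fold change (mutant over control, scaled RPKM + 0.1) of each measured member of the gene lists past the camera threshold and of 4 others, with filled points for members past the adjusted threshold of 0.05 and bars for list medians. Tubular injury has the highest median (2.18), proximal tubule the lowest (-1.41), and cell cycle sits at 0.00.

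Tubular injury genes were the highest group. Of 24 measured members 20 rose, 1 fell and 3 did not pass, 21 adjusted over the list alone. Havcr1 rose 46.6-fold, Plaur, the urokinase receptor, 12.9-fold, and the keratins Krt18 and Krt8 9.34-fold and 5.35-fold. Vcam1, an adhesion molecule, was the 1 that fell (log2 -0.76). The list was higher (camera, adjusted p = 3.06e-15; adjusted p = 0.0593 with an estimated correlation), with a median of 2.09 in the deep and 2.28 in the shallow libraries. Immediate early genes rose in 10 of 12 cases with 0 falling, 11 adjusted over the list alone: Atf3 9.24-fold, Junb 5.66-fold, Btg2 2.45-fold and Egr1 2.74-fold (camera, adjusted p = 4.06e-09; adjusted p = 0.0743 with an estimated correlation), with medians of 1.14 and 1.25. P53 and apoptosis genes rose in 10 of 14 cases with 0 falling, 10 adjusted over the list alone. Pmaip1, which encodes a proapoptotic protein, rose 14.4-fold, Plk2 3.91-fold, Perp 1.55-fold and Cdkn1a, a cyclin kinase inhibitor, 1.47-fold (camera, adjusted p = 1.56e-06; adjusted p = 0.0593 with an estimated correlation), with medians of 0.50 and 0.56. Of 9 heat shock genes 4 rose and 0 fell, with 4 adjusted over the list alone. Hspb1 rose 6.87-fold and Hsp90aa1 1.66-fold (camera, adjusted p = 0.0241; adjusted p = 0.172 with an estimated correlation), with medians of 0.22 and 0.22. The heat shock call was lost without male mutant replicate 1 (adjusted p 0.0561).

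Junction and adhesion genes rose in 12 of 18 cases and fell in 2, 14 adjusted over the list alone. The claudins Cldn4 and Cldn3 rose 6.01-fold and 4.81-fold, Itga3, an integrin, 3.74-fold and Cldn7 1.86-fold, while Cdh16, the kidney cadherin, fell 1.70-fold (camera, adjusted p = 0.000156; adjusted p = 0.19 with an estimated correlation). Medians were 0.52 and 0.40. Of 14 genes of the renin-angiotensin system and salt handling, 7 fell and 1 rose, 11 adjusted over the list alone. Ren1 fell 11.6-fold, Ace, the angiotensin-converting enzyme, 2.51-fold, Agtr1a 1.85-fold and Atp1b1 1.65-fold, and Agt, the angiotensinogen gene, rose 1.58-fold (camera, adjusted p = 0.0349; adjusted p = 0.557 with an estimated correlation). Medians were -0.40 and -0.44, and the call was lost without female control replicate 2 (adjusted p 0.0777), male control replicate 2 (0.052) or male mutant replicate 1 (0.0632), within the deep libraries (0.0562) and without genes that sit in other lists (0.0937).

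Secreted growth factors and cytokines rose in 20 of 30 cases and fell in 3, 26 adjusted over the list alone. Edn1, the endothelin 1 gene, rose 10.3-fold, Csf1, a macrophage growth factor, 7.76-fold, Hbegf 6.42-fold and Pdgfb 3.11-fold. Fgf1 (log2 -1.02), Bmp7 (-0.38) and Pdgfa (-0.35) fell. The list was higher (camera, adjusted p = 5.13e-09; adjusted p = 0.0761 with an estimated correlation), with a median of 1.06 in the deep and 0.93 in the shallow libraries. All 15 macrophage markers rose, 15 adjusted over the list alone. The complement genes C1qa, C1qb and C1qc rose 3.82-fold, 3.53-fold and 3.77-fold, and Fcgr1, an Fc receptor, by a log2 of 1.999 (camera, adjusted p = 8.77e-14; adjusted p = 0.0593 with an estimated correlation), with a median of 1.5 and 1.79.

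Other blood and immune lists did not pass by camera in the main fit, though by fry the lymphocyte (adjusted p 0.0154) and neutrophil (0.0239) lists did. Of 11 lymphocyte genes 5 rose and 1 fell, with 6 adjusted over the list alone. Cd3g rose 2.92-fold, Cd3e 2.09-fold and Cd4 1.56-fold, and Cd8a fell 3.46-fold (camera, adjusted p = 0.138; adjusted p = 0.535 with an estimated correlation). Of 9 neutrophil genes 2 rose and 0 fell, with 2 adjusted over the list alone: Ly6g rose 2.31-fold, while S100a8 (log2 0.73, adjusted p 0.091) and Cxcr2 (0.37, 0.0923) did not pass (camera, adjusted p = 0.107; adjusted p = 0.297 with an estimated correlation). Leaving out female control replicate 1 brought S100a8 past the threshold (0.0333). Of 9 erythroid genes 1 rose and 1 fell, with 2 adjusted over the list alone, and Alas2 (-0.39, 0.098) and Hbb-bt (-0.41, 0.138) did not pass (camera, adjusted p = 0.56; adjusted p = 0.747 with an estimated correlation). Leaving out male mutant replicate 2 brought Alas2 past it (0.0138). Haemoglobin reads were 0.0973 ± 0.0243% in controls and 0.0729 ± 0.0101% in mutants (SD, n = 4; exact permutation test, two-sided, p = 0.143). Of 17 interferon response genes 6 rose and 1 fell, 9 adjusted over the list alone: Ifit3 rose 2.72-fold, Ifit2 1.61-fold and Gbp2 1.86-fold, and Rsad2 fell 1.58-fold (camera, adjusted p = 0.0562; adjusted p = 0.565 with an estimated correlation). The interferon list lay near the threshold. It passed in the shallow libraries (0.00343, median 0.63, against 0.2 in the deep) and without female control replicate 1 (0.0193), female mutant replicate 1 (0.0412), male control replicate 1 (0.0343), male control replicate 2 (0.0445) or male mutant replicate 2 (0.0127). It also passed with library totals only (0.0493) and with no filter (0.0161). The neutrophil list passed in the shallow libraries (0.0115), without female control replicate 1 (0.0349) or female mutant replicate 2 (0.0494) and with no filter (0.0305). Medians in the deep and shallow libraries were 0.17 and 0.31 for lymphocytes, 0.46 and 0.52 for neutrophils and -0.26 and -0.05 for erythroid cells.

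In the glomerulus and vessels, podocyte genes fell in 7 of 14 cases with 0 rising, 10 adjusted over the list alone. Cdkn1c, a cell cycle inhibitor, fell 3.09-fold, Nphs1, the nephrin gene, 2.06-fold, Podxl 1.68-fold and Wt1 1.26-fold (camera, adjusted p = 0.00166; adjusted p = 0.297 with an estimated correlation), with medians of -0.33 and -0.49. Wt1 passed in neither batch alone (adjusted p 0.172 and 0.0518). Endothelial genes fell in 8 of 14 cases with 0 rising, 9 adjusted over the list alone: Plvap 1.66-fold, Tek 1.65-fold, Emcn 1.58-fold and Pecam1 1.44-fold (camera, adjusted p = 1.84e-05; adjusted p = 0.27 with an estimated correlation), with medians of -0.51 and -0.53. Of 11 juxtaglomerular and smooth muscle genes 2 rose and 3 fell, with 5 adjusted over the list alone. Akr1b7 fell 3.92-fold, Ren1 11.6-fold and Myh11 2.02-fold (camera, adjusted p = 0.179; adjusted p = 0.565 with an estimated correlation). Of 20 myofibroblast and matrix genes 6 rose and 2 fell, with 8 adjusted over the list alone. Timp1 rose 3.24-fold, Tagln 2.66-fold and Loxl1 1.86-fold (camera, adjusted p = 0.0987; adjusted p = 0.629 with an estimated correlation). Of 16 stromal genes 0 rose and 3 fell, with 3 adjusted over the list alone: Dcn fell 1.65-fold and Lamc3 1.51-fold, while Foxd1 (log2 0.34, adjusted p 0.0787) did not pass (camera, adjusted p = 0.259; adjusted p = 0.614 with an estimated correlation). Leaving out female mutant replicate 2 brought Foxd1 past the threshold (0.0134). The myofibroblast list passed in the deep libraries (0.0295) and without female control replicate 2 (0.0133), female mutant replicate 1 (0.0196) or male control replicate 2 (0.0445), and the smooth muscle list without female mutant replicate 2 (0.0474). Medians in the deep and shallow libraries were 0.25 and 0.11 for myofibroblasts, -0.15 and -0.06 for smooth muscle and -0.13 and -0.23 for stroma.

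Progenitor, urothelial and proliferation lists did not pass by camera in the main fit, though by fry the ureteric tip list did (adjusted p 0.0399). None of 23 cell cycle genes passed, with 0 adjusted over the list alone and a median of 0.00 (limma; 1 at unadjusted p under 0.05; camera, adjusted p = 0.896; adjusted p = 0.973 with an estimated correlation). The lowest p were those of Rrm2 (log2 0.27, adjusted p 0.0898), Ccnb1 (0.20, 0.191), Cdk1 (0.30, 0.193) and Tyms (-0.23, 0.293), and leaving out male mutant replicate 2 brought Cdk1 past the threshold (0.0475). Of 13 nephron progenitor genes Spock2 rose (log2 1.38), Crym (-1.46) and Itga8 (-0.60) fell, with 3 adjusted over the list alone, and Gdnf (-0.38, 0.102) did not pass (camera, adjusted p = 0.29; adjusted p = 0.614 with an estimated correlation). Of 15 early nephron genes 3 rose, among them Bmp2 (0.70), and 2 fell, among them Osr2 (-0.45), with 6 adjusted over the list alone (camera, adjusted p = 0.553; adjusted p = 0.864 with an estimated correlation). Of 9 ureteric tip genes 1 rose and 1 fell, with 2 adjusted over the list alone, and Etv4 (0.37, 0.0858) and Ret (-0.42, 0.107) did not pass (camera, adjusted p = 0.771; adjusted p = 0.864 with an estimated correlation). Etv4 passed without male mutant replicate 2 (0.0452) and Ret without male control replicate 1 (0.00887). Of 9 urothelial genes Upk3b rose 8.70-fold and 3 fell, among them Upk3a 1.85-fold and Upk2 2.41-fold, with 4 adjusted over the list alone (camera, adjusted p = 0.0933; adjusted p = 0.557 with an estimated correlation). The urothelium list passed in the deep (0.0455) and shallow (0.0288) libraries each alone, with medians of -0.92 and -0.57, and without female control replicate 1 (0.0186) or male mutant replicate 2 (0.0487). The early nephron list had medians of 0.03 and -0.34 in the deep and shallow libraries and passed in the shallow ones (0.0107). Signs also differed between the batches for the ureteric tip (0.1 and -0.17) and the cell cycle (0.08 and -0.13), and medians were -0.17 and -0.32 for nephron progenitors.

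Lists for tissues beside the kidney did not pass by camera over all libraries. Of 7 adrenal genes Mc2r rose (log2 0.94) and Chga fell (-1.07), with 2 adjusted over the list alone, and Cyp11a1 (-0.41, adjusted p 0.148) and Nr5a1 (-0.20, 0.28) did not pass (camera, adjusted p = 0.837; adjusted p = 0.864 with an estimated correlation). The median was 0.08 and the mean -0.05, and the medians in the deep and shallow libraries were 0.07 and -0.03. Of 10 adipose genes Lep rose (1.07) and 1 fell, with 1 adjusted over the list alone, and Cidec (0.94, 0.479) and Cfd (1.21, 0.613) did not pass (camera, adjusted p = 0.62; adjusted p = 0.864 with an estimated correlation). The adipose median was -0.93 in the deep and 2.14 in the shallow libraries, so its sign differed between batches. The list passed in the shallow ones by camera at the preset correlation of 0.01 (adjusted p 8.59e-07). Its members varied together, with an estimated correlation of 0.714 over all libraries, so this value overstates the evidence for the list. Leaving out 1 library moved Cidec between 0.12 (without female mutant replicate 2) and 1.63 (without male mutant replicate 1), and Cfd between 0.16 and 2.69 (without the same libraries). Of 5 skeletal muscle genes Acta1, an actin, rose 9.35-fold, Tnni2 rose (0.90) and Actn3 fell (-0.85), with 3 adjusted over the list alone, and Tnnt3 (-0.28, 0.261) did not pass (camera, adjusted p = 0.553; adjusted p = 0.647 with an estimated correlation). Its median was -0.02 and its mean 0.60, with -0.13 in the deep and 0.09 in the shallow libraries. Of 9 nerve and glia genes Tubb3 (1.19) and Mbp (0.58) rose and 1 fell, with 4 adjusted over the list alone, and Prph (0.66, 0.0706) did not pass (camera, adjusted p = 0.516; adjusted p = 0.684 with an estimated correlation). Prph passed without male control replicate 1 (0.00795), and the list median was 0.00 in the deep and 0.12 in the shallow libraries.

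Some calls in these lists were borderline, and most of them were lost on removal of any of several libraries, with changes of similar size: 0.189 to 0.267 for Pax8, 0.263 to 0.3 for Ptprc and 0.319 to 0.43 for Ccnd1. Avpr1a fell (log2 -0.47) and Pappa2 rose (0.97) in the macula densa list. Avpr1a was lost without female control 1, female mutant 2, male control 2 or male mutant 1 (adjusted p 0.0545 to 0.0732). Pappa2 was lost without any single library except female control 2 and female mutant 2 (0.098 to 0.117). Among early nephron genes, Sfrp2 (-0.44) was lost without female mutant 2, male control 2 or male mutant 2 (0.0558 to 0.0682), Ccnd1 (0.42) without any but female control 2 and female mutant 2 (0.0535 to 0.102), and Pax8 (0.24) without any but female mutant 2 (0.056 to 0.139). Wnt11 (-0.53) was lost without any but female control 2 and female mutant 1 (0.0568 to 0.0984), and Upk1a (-0.87) without female mutant 1 or male mutant 1 (0.0535 to 0.0549). Lum (-1.51) was lost without female control 2, female mutant 1 or either male mutant library (0.0556 to 0.0621). Cthrc1 (-0.57) was lost without female mutant 2, male control 2 or either male mutant library (0.0509 to 0.0688), and Col3a1 (-0.44) without either female control library, female mutant 1, male control 2 or male mutant 1 (0.0523 to 0.123). Cnn1 (0.44) was lost without female control 1, female mutant 2, male control 2 or male mutant 2 (0.0698 to 0.0836), and Smtn (0.45) without any but female control 2 and male control 1 (0.0502 to 0.0951). Cd3d (1.17) was lost without male mutant 2 (0.0519), Ptprc (0.29) without any but male control 1 (0.0514 to 0.0833), and Csf3r (0.50) without female control 2, female mutant 2, male control 1 or either male mutant library (0.0669 to 0.0777). Hba-a1 (-0.73), which has a near-identical copy, was lost without female mutant 2 (0.0591), and Epb42 (0.76) without female mutant 2 or male mutant 1 (0.0608 to 0.062). Fabp4 (-0.58) was lost without female control 1 or any mutant library (0.0572 to 0.115), and Gap43 (-0.86) without male mutant 2 (0.0634). Dnajb1 (0.31) was lost without male control 2 or male mutant 1 (0.0502 to 0.0509), and Hspa8 (0.37) without female control 1, either female mutant library, male control 2 or male mutant 2 (0.056 to 0.116). Cldn8 (-0.34) was lost without any but female mutant 1 (0.0546 to 0.114). Dock5 (0.74) was lost without female mutant 2 or male mutant 2 (0.0507 to 0.0545), Nt5e (0.57) without those or male control 2 (0.0609 to 0.0666), and Scnn1b (-0.42) without female mutant 2, male control 2 or male mutant 1 (0.0507 to 0.0582). The numbers after the groups are replicate numbers. Gap43 was also lost with no sex term (0.0663), Cd3d by voom (0.05) and with a pseudocount of 0.01 (0.0829), and Pappa2 with a pseudocount of 1 (0.0515). With no filter, Pappa2, Ccnd1, Wnt11, Cthrc1, Csf3r, Fabp4, Cldn8, Pax8, Smtn and Col3a1 were lost (0.0535 to 0.089), Pax8 and Col3a1 also with library totals only (0.0527 and 0.0542), and Pax8 with median-of-ratios scaling (0.0527). Gdnf passed by voom (0.0411), and Fjx1 with library totals only (0.0432) and with no sex term (0.0352).

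Other named calls held without any 1 library but not within 1 depth batch, where 4 libraries remain. In the deep libraries adjusted p was 0.0624 for Kcnj16, 0.0928 for Abca13, 0.0589 for Slc8a1, 0.152 for Osr2, 0.177 for Upk2, 0.232 for Lamc3, 0.0753 for Mc2r, 0.0528 for Gbp2, 0.15 for Bmp7 and 0.102 for Agt. In the shallow ones it was 0.0593 for Crim1, 0.299 for Trpm6, 0.135 for Ptgs2, 0.0907 for Bmp2, 0.1 for Dcn, 0.341 for Cd4, 0.0548 for Actn3 and 0.127 for Mbp. Pdgfa passed in neither (0.0592 and 0.142). All kept their sign. S100a8 passed in both batches alone (0.0198 and 0.000225), Ptpn14 in the deep one (0.03), and Prph (0.00943), Cidec (0.000151) and Cfd (1.55e-08) in the shallow one.

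Over the 36 lists tested, 19 passed with a preset correlation, 9 higher and 10 lower, 0 passed with an estimated correlation (lowest adjusted p 0.0593), and 24 passed by fry. Fry tests a list's mean change against no change and, unlike camera, makes no comparison with the other genes. Fry added the juxtaglomerular and smooth muscle (adjusted p 0.0122), skeletal muscle (0.0133), lymphocyte (0.0154), neutrophil (0.0239) and ureteric tip (0.0399) lists. Called genes went both ways in smooth muscle (2 higher, 3 lower), skeletal muscle (2 and 1), lymphocyte (5 and 1) and ureteric tip (1 and 1). In the neutrophil list 2 were higher and 0 lower. Other splits of the 8 libraries gave up to 24 lists past the threshold. Those that gave 19 or more had unequal numbers of mutants and controls on each side and so keep part of the genotype difference. Comparing the number of lists over splits therefore does not decide whether it reflects genotype. In a comparison added after the results were seen, 21 lists, all 19 among them, had their largest median in size at the genotype split. Each of the 34 other splits gave a smaller median for these lists. The exact permutation p was 0.0286 for each list, the smallest possible, and 0.049 adjusted over the lists. All 21 lists share this adjusted value, which lies under 0.05 because so many of them tie at the smallest p. Some lists share members, so they are not independent. The adjusted value is therefore not evidence for any given list.

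The genotype effect was then asked in each sex. In males 2768 genes passed, 1425 higher and 1343 lower, and in females 2129 passed, 1092 higher and 1037 lower (limma). Leaving out 1 library moved these counts to as few as 1330 in males (without male mutant replicate 2) and 882 in females (without female mutant replicate 2). Ankrd1 changed by a log2 of 6.39 in males and 6.30 in females. The 2 sets of log2 changes correlated at 0.823 across genes, which are not independent replicates, and all 4745 genes called over both sexes had the same sign in each, the sexes being subsets of the same libraries. Of 1724 genes called in both sexes separately, 1723 had the same sign. Gm36130, a gene model chosen after its values were seen, was the other, at 2.57 in males and -4.22 in females. No gene passed the test of the difference between the sexes (limma, 0 genes, lowest adjusted p 0.151; 554 at unadjusted p under 0.05; 0 by voom). With 2 libraries per group, simulated 2-fold differences were found in 7.69% of cases, so differences of that size were mostly not detectable. Gm36130 passed it with pseudocounts of 0.5 (adjusted p 0.0161) and 1 (0.0178) and without male control replicate 1 (0.017), Gm12666 without male mutant replicate 1 (0.00837) and Gm29779 without male mutant replicate 2 (0.024).

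**Figure D3:**
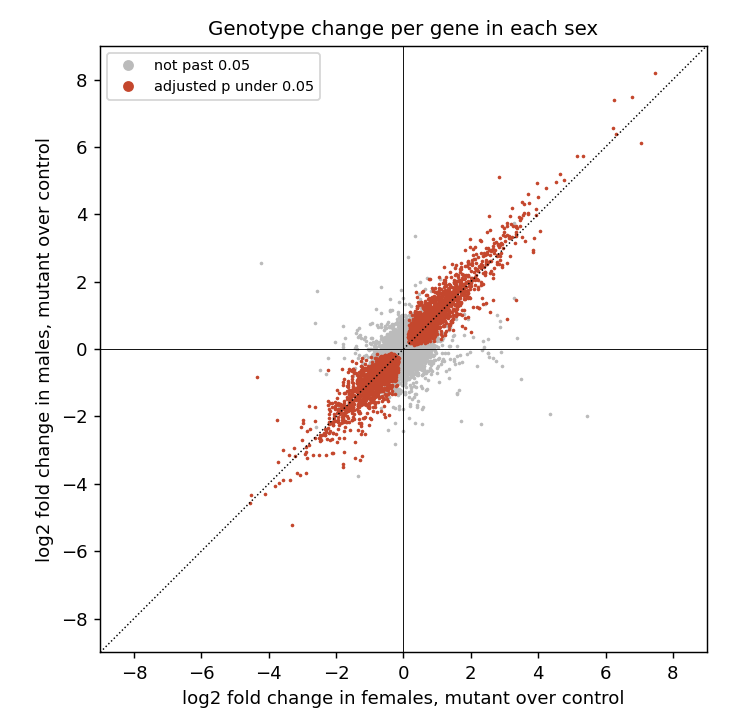
Log2 fold change (mutant over control) of each tested gene in females (horizontal axis) and males (vertical axis), colored where the genotype effect over both sexes passed the adjusted threshold of 0.05. The changes correlate at 0.823 across 18156 genes, and the dotted line marks equal change.

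Few genes passed the threshold for sex at this age. In the simulation 37.5% of 1.5-fold sex changes were recovered, so small differences could be missed. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were higher in male libraries, by log2 6.72, 6.81, 4.19 and 4.33, and Xist and Tsix, which overlap on opposite strands of the X chromosome, were lower by -3.94 and -2.44. These were the 6 genes past the threshold (limma). Ddx3y was at 13.4 ± 1.27 scaled RPKM in males and 0.0302 ± 0.0315 in females (SD, n = 4), so all libraries matched their labelled sex. Xist was at 2.11 ± 0.724 in females and 0.0436 ± 0.0478 in males, and lost its call by voom (adjusted p 0.0927) and with a pseudocount of 0.01 (0.0938). The X-linked partners were lower in males without passing: Kdm6a (-0.58, adjusted p 0.457), Eif2s3x (-0.65, 0.096), Ddx3x (-0.19, 1) and Kdm5c (-0.48, 1). At unadjusted p under 0.05 there were 504 genes. Split by replicate number, the same libraries gave 58 genes.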

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

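The tests of explanations below were all written after the results were seen. Bootstrap standard errors come from 2000 resamplings of the genes of each list. They treat genes as independent and do not measure the spread between libraries.

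Yap1 was level between genotypes while YAP/TEAD target genes were higher. The targets argue against a single library with the wrong genotype label. The lowest mutant mean log2 level over the list lay 1.225 above the highest control mean, against a widest range of 0.213 within a genotype. An exchange of all genotype labels would leave a gap of the same size, so the gap does not exclude it. The interval of the Yap1 fold, 0.871 to 1.16, leaves open that transgene reads were not counted as mouse Yap1 (lower bound 0.871). It also leaves open a rise confined to a small share of the cells (upper bound 1.16).

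Proximal tubule genes were lower in mutants although the Cre allele is named for a distal gene. Dilution by RNA of other cells would lower endothelial genes as much, but the proximal tubule median lay -0.907 from the endothelial median (bootstrap standard error 0.254). The endothelial median was itself -0.501, so dilution as a part of the fall is not excluded. Sequencing depth is unlikely as the cause, since the smaller of the falls within the deep and shallow libraries was -1.386. An even loss of proximal tubule cells is left open, as the members' changes had an SD of 0.881 against a median standard error of 0.167, which is uneven, but members that other cells also express would fall less under an even loss.

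Macrophage genes were higher in mutants. Blood left in the kidneys would raise erythroid genes, whose median lay -1.813 from the macrophage median (bootstrap standard error 0.281). A lower share of epithelial RNA would raise stromal genes as well, whose median lay -1.828 from it (bootstrap standard error 0.184).

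Each count was compared over 34 splits of the 8 libraries into 4 and 4, the real one among them. The genotype count of 4745 was reached by 1 split, itself, and the highest other count was 15, at the split by replicate number. Every other split puts mutants and controls on the same side, so the genotype difference adds to the spread within its groups. Low counts were bound to follow there, so the comparison does not exclude chance. The sex count of 6 was reached by 2, itself among them, so the count alone does not exclude chance. The other was the split by replicate number, with 58, which points to a structure of the libraries by replicate number, whether from depth or from something else the number marks, and every remaining split gave at most 2 genes. With replicate number as a block the sex count was 7. Of the 6 genes, 4 are Y-linked and were higher in males: Ddx3y, Eif2s3y, Kdm5d and Uty. Their log2 differences were 6.72, 6.81, 4.19 and 4.33 (standard errors 0.18, 0.287, 0.124 and 0.116). These values argue against chance for the Y-linked genes. The count of 19 lists was reached by 10, itself among them, with 24 the highest other. All the others that reached it had unequal numbers of mutants and controls on each side, so they keep part of the genotype difference. Such unequal splits gave 11 to 24 lists. Splits with equal numbers on each side gave 0 to 8, but there the genotype difference adds to the spread. The comparison therefore does not decide whether the number of lists could arise by chance.

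Single libraries far from the other 3 of their genotype were seen in 14 of 426 groups, against 21 expected at 1 in 20. Among controls, the share of the range taken by the gap was 0.893 for Serpinb9b (male control replicate 2, low), 1 for Il24 (female control replicate 2, high), 0.829 for Krt7 (male control replicate 1, high) and 0.851 for C1qc (male control replicate 2, low). It was 0.834 for Hbb-bt, at 74.6 in male control replicate 2 against 119 to 131 in the others. It was 0.866 for Tubb3 (female control replicate 1, low), 0.973 for Igfbp3 (male control replicate 1, high) and 0.902 for Tgfb2 (female control replicate 2, high). Among mutants it was 0.925 for Nphs1 (female mutant replicate 2, low), 0.926 for Ly6g (the same library, high), 0.879 for Lep (male mutant replicate 2, high), 0.837 for Atf3 (the same library, high), 0.927 for Cldn7 (female mutant replicate 1, low) and 0.924 for Cd3d (male mutant replicate 1, low). Counting noise limits 2 of the control flags: Il24 had 1 read in female control replicate 2 against 0 in the others, and Serpinb9b had 2 reads in male control replicate 2.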

How the results depend on the processing

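The pseudocounts, the depth batches and camera without a variance trend were chosen after the results were seen. The genotype effect gave 2202 genes with a minimum change of 1.2-fold and 3110 in the shallow libraries, and 3599 to 4770 with 1 library left out. Males gave 1330 to 2677 and females 882 to 2337 with 1 left out, where a lone sample is assumed to vary like the other groups. The interaction gave 1 gene with a replicate block, with pseudocounts of 0.5 and of 1, and 0 to 1 with 1 library left out. That gene was Gm36130 under the block (adjusted p 0.00982) and under the pseudocounts (0.0161 and 0.0178). With the block, genotype gave 5473 genes, males 3674, females 3000, sex 7 (Eif2s3x added, adjusted p 0.0249) and lists 21. The block brought S100a8 (0.00386), Axl (0.0184), Fjx1 (0.0294), Foxd1 (0.0421), Etv4 (0.0429) and the neutrophil (0.034) and urothelium (0.0409) lists past the threshold. Deviations of same-numbered libraries correlated at 0.067, 0.379, 0.309, 0.108, -0.003 and 0.247 over the 6 pairs of groups, not all over 0.1. Library names in the labels run in 1 series per number, but the labels do not say that a number marks a shared litter, batch or day, so the numbers were not treated as pairs. Lists gave 0 with an estimated correlation and 17 to 22 with 1 library left out. Yap1 was -0.116 in the shallow libraries and -0.079 to 0.065 with 1 left out. Signs turned for Cfd by voom (-0.627) and in the deep libraries (-1.036), and there also for Cidec (-0.557), Arhgef17 (0.104), Asap1 (0.145), Rbms3 (0.01), Cnnm2 (0.085), Sall3 (0.074) and Atp2b1 (0.002), none of which had passed. With 1 library left out, Arhgef17 ran from -0.159 to 0.048, Asap1 from -0.125 to 0.042, Rbms3 from -0.057 to 0.041 and Cnnm2 from -0.127 to 0.045. Of 4383 values for 210 named genes, 4155 were the same, 184 weaker, 24 stronger and 20 reversed, and the cause was not tested. DESeq2 was planned and not run, and voom was the model run on the recovered reads.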

Other observations

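The family scan and the segment comparison below were both chosen after the results were seen.

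Gene families grouped by symbol also changed, and they share members with the gene lists (Aqp4 and Aqp6, for example), so they are not independent of them. Of 268 families with at least 8 genes, 33 passed (camera, 13 higher and 20 lower), and 0 passed with an estimated correlation. Aldehyde dehydrogenases (Aldh) fell in 14 of 19 genes, with a median log2 change of -0.71 (adjusted p = 2.19e-05; adjusted p = 0.646 with an estimated correlation). Aquaporins (Aqp) fell in 6 of 9 (-0.76, 0.00074; 0.638) and carbonic anhydrases (Car) in 7 of 12 with 1 higher (-0.75, 0.000724; 0.638). The Cox symbols fell in 10 of 24 (-0.41, 0.0012; 0.952). Annexins (Anxa) rose in 8 of 11 (0.61, 0.000329; 0.646), chemokines of the Ccl group in 9 of 16 (0.98, 0.000329; 0.638) and Toll-like receptors (Tlr) in 8 of 11 (0.75, 0.0123; 0.952). The genotype split gave the largest median of all 35 splits for 26 of the 33 families, these 7 among them (exact permutation p = 0.0286, and 0.111 adjusted over the 268 families), and for the other 7, such as Rpl and Tnfrsf, another split gave one as large.

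Whether the fall is largest in the segment that carries Slc12a3 was compared by list medians. The distal convoluted tubule median minus the proximal tubule median was 0.377 (bootstrap standard error over the genes of the lists 0.301), which leaves open whether the segments differ.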
